A study of Mus musculus with 12 samples.

How the data were processed

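Liver RNA of single mice on the CL diet was measured by RNA sequencing of polyadenylated RNA. Per the labels' protocols, libraries were made with dUTP marking of the second strand and sequenced as pairs. Whether the counting used strand is not given in the sources used here, so reads of overlapping genes and antisense partners could not be told apart. Groups were taken from the sample labels (genotype and title). Replicates are separate animals by number in the titles. The labels describe 12 samples in 4 groups of 3. Values of 6 samples in 2 groups (WT replicates 62, 63 and 64; CCR1-KO replicates 65, 66 and 67) were used; the other 6 were not analysed here. No column of other samples was used.

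Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, with no roles stated. The deposited table gives, per the file headers, a read count and an FPKM value per gene and library. The counts are whole numbers that were not normalized, and were used as deposited. The deposited FPKM values (fragment numbers scaled to gene length and library size) followed the counts by 1 factor per library: over 3308 genes with at least 2000 reads in every library, the SD of the log2 ratio relative to the first library was at most 0.00097. Even numbers made up 50.5% to 51.3% of counts above 0. The table has 27912 genes, each with a symbol, and 55 symbols belong to more than 1 gene. The notes list the human build GRCh38, but the identifiers are of mouse: 27839 were found in GENCODE M21 (GRCm38), and 25059 of these, 90.0%, had the same start, end and strand. Coordinates are therefore given as GRCm38, as the table has them. How the authors assigned reads that match several genes is not given, so values of near-identical families (Mup, Gstm, Gsta, Cyp2a, Serpina) and of overlapping models are uncertain.

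The design written before the data were examined assumed FPKM values for 12 libraries in 1 limma fit. Because counts were found, for 6 libraries, the main test became edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood functions glmQLFit and glmQLFTest on the counts. The limma fit on log2(FPKM + 0.5), for genes with FPKM of at least 0.5 in 3 libraries, became an alternative. Genes were kept by filterByExpr (minimum count 10, minimum total 15), leaving 17729. TMM scaling factors were 1.06, 1.12 and 1.17 for WT and 1.06, 0.874 and 0.779 for CCR1-KO replicates 65, 66 and 67. CPM values use these factors. SE is the absolute log2 fold change over the square root of the F statistic. The threshold was an adjusted p (Benjamini-Hochberg) under 0.05. For a gene without reads in 1 group, a bound was computed against 3 counts over the group. Intervals and floors cover counting error only. Replicate pairs were compared by a chi-square of their counts; its value per degree of freedom was at least 68.7, so each pair differed by more than sampling noise.

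Before the data were examined, 47 gene lists were fixed from general knowledge of liver, diet, macrophages, mTORC1, other tissues and RNA quality. The 46 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over lists. With the correlation estimated for each list, 0 of the 46 passed (smallest adjusted p = 0.27), against 23 at the preset value. Unadjusted p was under 0.05 for 5 lists with the estimated correlation and for 25 at the preset value. Directional fry, which asks whether the genes of a list move one way and does not compare them with other genes, passed 9 lists, 8 of them among the 23. GO, KEGG and Reactome terms that the table pairs with genes were tested with camera where 10 to 300 members were tested (4867 terms). Genes were named by a rule fixed in advance: Ccr1; the 10 higher and 10 lower genes of largest fold change among those with adjusted p under 0.05, groups that do not overlap and a mean FPKM of at least 1 in the higher group; and up to 4 members of smallest p per list. Predicted models, pseudogenes and antigen receptor variable segments were left out of the naming. Where 5 or fewer members of a list passed, all were named, and those beyond the 4 were chosen after their values were seen. So were Alb, Cyp7a1, Nnt as a pair of models, Lpin1, Mlxipl, Cyp2b13, Ntrk2, Lpl, Cd36 and the genes of the clock, fasting and substrain tests. Some genes that these rules would name are not reported here.

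The count test was tested on simulated counts drawn from the means, dispersions and library sizes of these libraries (CCR1-KO against WT, 17150 genes, 200 changed). It recovered 24.0% of 100 genes changed 2-fold and 58.0% of 100 genes changed 4-fold, with 10 false calls among 92 (limma 13 among 81, DESeq2 50 among 174), so many changes of 2-fold would be missed at this sample size. With 1 list moved 2-fold, camera at the preset correlation called 3 of 46 lists, that list among them. The simulated genes were drawn independently of each other. In the data the estimated correlation ran from -0.12 (adipose tissue list) to 0.95 (mitochondrially encoded messenger RNA list). The simulation therefore does not measure false list calls among correlated genes. Alternatives fixed before the data were examined were other pseudocounts, filters and scalings of FPKM, robust and weighted limma fits, each replicate left out in turn, and estimated correlation and fry for lists. Added after seeing the data were the limma fit on 6 libraries itself, other edgeR scalings and filters, a robust quasi-likelihood fit, DESeq2 1.42.0, and a fit without Mup, mitochondrial and 18S rRNA genes, as was every alternative for the annotation terms. Planned fits that need the other 6 libraries (a fit for each set, all WT libraries as 1 control, and the comparisons of the LKO group) were not run. Permutation tests were exact and two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.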

Results

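Bulk RNA sequencing was used to compare livers of CCR1 knockout mice with livers of wild-type (WT) mice. CCR1 is a receptor for inflammatory chemokines such as CCL3 and CCL5. Male C57BL/6 WT and CCR1 knockout mice, 8 weeks old at the start, ate a diet rich in fat and cholesterol with added cholate (the CL diet) for 12 weeks. The series holds 12 libraries in 4 groups of 3. Expression values of 6 libraries were used here: WT replicates 62, 63 and 64, and CCR1-KO replicates 65, 66 and 67. The other 6 libraries (WT replicates 76, 77 and 80, and the group labelled LKO, replicates 83, 85 and 87) were not analysed here, and no comparison involves them. Chow-fed livers were not analysed here either, so each difference below is between the WT and CCR1-KO groups on the same diet. Genotype and genetic background cannot be separated in these 6 libraries, as the last part describes. Library totals ran from 74699391 to 79154085 reads assigned to genes, with 77481894 ± 1975755 in WT and 75542295 ± 1098963 in CCR1-KO (SD, n = 3). At these totals 1 read corresponded to between 0.0113 and 0.0167 CPM, the unit of read counts scaled to an equal library size. Values below are CPM, mean ± SD, with CCR1-KO given first and n = 3 in each group, or log2 fold changes of CCR1-KO over WT ± standard error (SE). Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 17729 genes, unless a gene list is named.

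The first question was whether the targeted transcript was lower in the libraries labelled as knockout. Ccr1 (ENSMUSG00000025804, chromosome 9, 123962124 to 123968692, minus strand, GRCm38) had 11, 4 and 14 reads in CCR1-KO replicates 65, 66 and 67, and 100, 23 and 123 reads in WT replicates 62, 63 and 64. Scaled, this was 0.144 ± 0.0867 against 0.958 ± 0.611 CPM, so the CCR1-KO mean was 15.1% of the WT mean. Every CCR1-KO library lay below every WT library, but WT replicate 63, at 0.260 CPM, lay close to CCR1-KO replicate 67, at 0.234 CPM. The log2 fold change was -2.72 ± 0.76, adjusted p = 0.075, which missed the threshold of 0.05. The exact two-sided permutation test gave p = 0.10, the smallest that 3 against 3 libraries allow. With so few reads, counting error alone is wide: the exact 95% interval was 14.6 to 34.5 reads in WT replicate 63 and 7.65 to 23.5 in CCR1-KO replicate 67. Which part of the gene was deleted is not given in the sources used here, so residual reads could not be assigned to it. Beside Ccr1, Ccr2 gave 1.17 ± 0.948 against 6.10 ± 2.59 CPM (log2 fold change -2.37 ± 0.58, adjusted p = 0.053). In the fixed list of 23 tested genes of that part of chromosome 9, Pth1r, more than 5 Mb from Ccr1 (chromosome 9, 110722085 to 110747145), was the one gene past the threshold over all genes (log2 fold change -0.74 ± 0.16, adjusted p = 0.042), while 2 were lower adjusted over the list alone. The list as a whole did not pass (median 0.08, camera adjusted p = 0.71, mean -0.14).

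**Figure D1:**
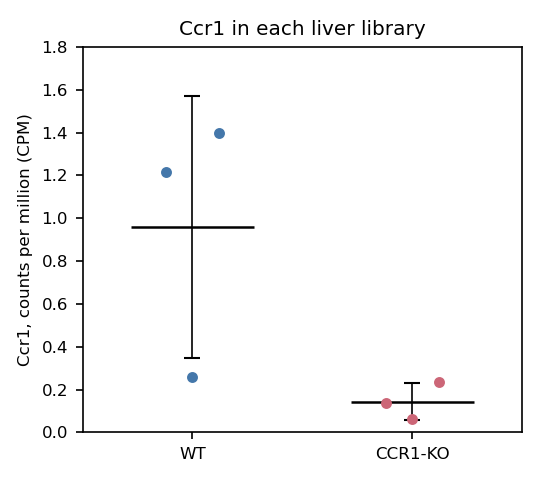
Ccr1 expression in CPM (vertical axis, linear, from 0) in each liver library of the WT and CCR1-KO groups (horizontal axis). Points are libraries, the long line is the group mean and the error bar is 1 SD (n = 3). The CCR1-KO libraries lie below the WT libraries, with WT replicate 63 at 0.260 CPM close to CCR1-KO replicate 67 at 0.234 CPM.

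Across the liver transcriptome, 501 genes were higher and 640 were lower in CCR1-KO than in WT, 1141 of 17729 tested. Hsd3b5, a hydroxysteroid dehydrogenase that is typically male-biased in mouse liver (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252), reached 165 ± 110.2 against 0.594 ± 0.240 CPM (log2 fold change 8.11 ± 0.81, adjusted p = 0.0049). Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1 (chromosome 13, 35958839 to 35970388), reached 20.9 ± 11.3 against 0.0386 ± 0.00584 CPM (log2 fold change 9.02 ± 0.67, adjusted p = 0.0022). The lipocalin Obp2a rose by 5.46 on the log2 scale. The other 7 of the 10 largest increases were major urinary protein genes of one cluster on chromosome 4 (Mup1, Mup5, Mup7, Mup8, Mup13, Mup15 and Mup17). These genes are near-identical copies, so how reads were split between them is uncertain. Of 21 Mup genes tested, 15 rose and none fell. Their summed share of all reads was 1.09% ± 0.0690 in WT and 10.7% ± 6.56 in CCR1-KO, with 3.46%, 12.5% and 16.2% in CCR1-KO replicates 65, 66 and 67. No WT read was assigned to Mup5, which was at least 7210.4-fold higher in CCR1-KO against a floor of 3 counts over the WT group.

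Among the 10 largest decreases were Sprr1a, a small proline-rich protein of injured epithelium (0.0598 ± 0.0566 against 6.15 ± 2.01 CPM, log2 fold change -6.59 ± 0.68, adjusted p = 0.0058). Timp1, an inhibitor of matrix metalloproteinases, was another (0.119 ± 0.103 against 2.27 ± 1.65 CPM, log2 fold change -4.20 ± 0.91, adjusted p = 0.038). The peroxisomal oxidase Hao2 (log2 fold change -5.49 ± 0.71, adjusted p = 0.0098), the imprinted fetal transcript H19 (log2 fold change -4.87 ± 0.52, adjusted p = 0.0065) and the surface marker Ly6d (log2 fold change -4.93 ± 0.81, adjusted p = 0.018) also fell. Gsta1, a glutathione transferase with close paralogs, fell by 4.24 on the log2 scale, and Cyp2a22, a cytochrome P450 with close paralogs, fell by 4.07. Sdcbp2 fell by 4.06 and Slc35f2 fell by 3.89. The remaining one was 1 of 2 overlapping models of Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase. This model (ENSMUSG00000116207, chromosome 13, 119335528 to 119408952) had 25.3 ± 5.10 CPM in WT and no read in CCR1-KO, at least 1728-fold lower against a floor of 3 counts over the group. The other Nnt model (ENSMUSG00000025453) was higher, at 140.5 ± 10.8 against 39.3 ± 6.51 CPM. The split of reads between the models is uncertain, but their sum was higher in CCR1-KO too (140.5 ± 10.8 against 64.6 ± 1.41 CPM). Whether the Nnt difference follows genotype or genetic background cannot be told apart here, as the last part describes. Of the 1141 changed genes, 1140 had groups that did not overlap, which a threshold on the same values favours. Of all tested genes 32.6% had such groups, where chance gives 10% for a single gene. Genes are correlated and the share was not computed for other groupings of the 6 libraries, so its excess was not tested. The spread within groups was wide (biological coefficient of variation 0.302). The count fell to 202, 102 and 163 genes without WT replicates 62, 63 and 64, and to 331 and 395 without CCR1-KO replicates 66 and 67, while it rose to 2419 without CCR1-KO replicate 65. Of the 1141 genes, 50 passed in 0 of these 6 fits and 637 in 1. In all 6 of them 85 passed, 29 higher and 56 lower, and Hsd3b5, Ppp1r3g, Mup5, Sprr1a, Hao2, H19 and Slc35f2 were among them. Of the other largest increases, Mup1 and Mup8 passed in 1 of the 6, Mup7 and Obp2a in 2, Mup13 and Mup15 in 3 and Mup17 in 4. Of the other largest decreases, Timp1 and Gsta1 passed in 1 of the 6, Cyp2a22 and Sdcbp2 in 2 and Ly6d in 3. The balance of directions rested on scaling: 43.9% of changed genes were higher, but 17.0% in the limma fit on deposited FPKM, where the median of all genes shifted by -0.23, and 20.4% with no scaling factors (shift -0.30).

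Cholesterol synthesis genes were lower in CCR1-KO livers. Of 25 tested genes of cholesterol synthesis and uptake, 15 fell, 0 rose and 10 did not pass. Adjusted over the list alone, 19 were lower (median log2 fold change -1.26, camera adjusted p = 1.5e-17, and adjusted p = 0.31 with an estimated correlation). Hmgcs1, the cytosolic HMG-CoA synthase, fell to 62.1 ± 15.1 against 394 ± 134 CPM (log2 fold change -2.67 ± 0.30, adjusted p = 0.0085). Mvd, the mevalonate decarboxylase, had 3.40 ± 0.720 against 14.7 ± 4.20 CPM (log2 fold change -2.11 ± 0.27, adjusted p = 0.0098). Sc5d, an enzyme of late sterol synthesis, had 166 ± 23.7 against 370.0 ± 53.8 CPM (log2 fold change -1.15 ± 0.17, adjusted p = 0.013). Hmgcs1 and Mvd passed in every fit that left out 1 library. Hmgcs1 lies within 5 Mb of Nnt, as the last part describes.

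Most lipid-storing genes that changed were lower as well. In the lipogenesis list 13 of 30 tested genes fell, 3 rose and 14 did not pass. The count was 17 lower and 4 higher adjusted over the list alone (median log2 fold change -0.74, camera adjusted p = 2.1e-06, and adjusted p = 0.27 with an estimated correlation). Pparg, a nuclear receptor that drives fat storage, fell to 6.65 ± 0.859 against 21.5 ± 2.31 CPM (log2 fold change -1.69 ± 0.15, adjusted p = 0.0034). The fatty acid synthase Fasn fell to 78.9 ± 12.6 against 180.2 ± 21.3 CPM (log2 fold change -1.19 ± 0.16, adjusted p = 0.011). The elongase Elovl5 fell to 275 ± 54.7 against 695 ± 62.8 CPM (log2 fold change -1.34 ± 0.17, adjusted p = 0.0098). Those that rose included Lpin1 (log2 fold change 3.40), a phosphatidate phosphatase, and Mlxipl (log2 fold change 0.93), which encodes the carbohydrate-response factor ChREBP. In the list of lipid droplet and lipid uptake genes, 6 of 33 tested fell, 0 rose and 27 did not pass. Of the same genes, 9 were lower adjusted over the list alone (median log2 fold change -0.50, camera adjusted p = 1.2e-06, and adjusted p = 0.27 with an estimated correlation). The lipid droplet protein Cidec fell to 7.99 ± 2.63 against 67.05 ± 15.8 CPM (log2 fold change -3.07 ± 0.28, adjusted p = 0.0033), Hsd17b13 to 369.6 ± 13.1 against 715 ± 47.4 CPM. The fatty acid carrier Fabp4 fell to 7.66 ± 1.79 against 17.3 ± 0.771 CPM and the droplet coat protein Plin3 to 22.8 ± 2.86 against 40.5 ± 6.52 CPM. Of the 33 genes, 11 also stood in other lists. Fabp4, Lpl and Cd36, lower here, count as lower in the list of lipid-associated macrophages below as well. Cidec and Pparg passed in every fit that left out 1 library, while Fabp4 and Plin3 lost the call in 4 and 5 of the 6. The list of fatty acid oxidation and PPAR-alpha targets did not pass as a whole (median -0.0031, camera adjusted p = 0.99). Of its 40 tested genes Angptl4 rose (log2 fold change 1.10 ± 0.15, adjusted p = 0.012), Ucp2 fell (log2 fold change -1.53 ± 0.27, adjusted p = 0.023) and Hadh fell (log2 fold change -0.63 ± 0.15, adjusted p = 0.049), and the other 37 did not pass. With 1 library left out, Hadh passed in 0 of the 6 fits and Ucp2 in 1. There were 1 higher and 2 lower adjusted over the list alone.

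**Figure D2:**
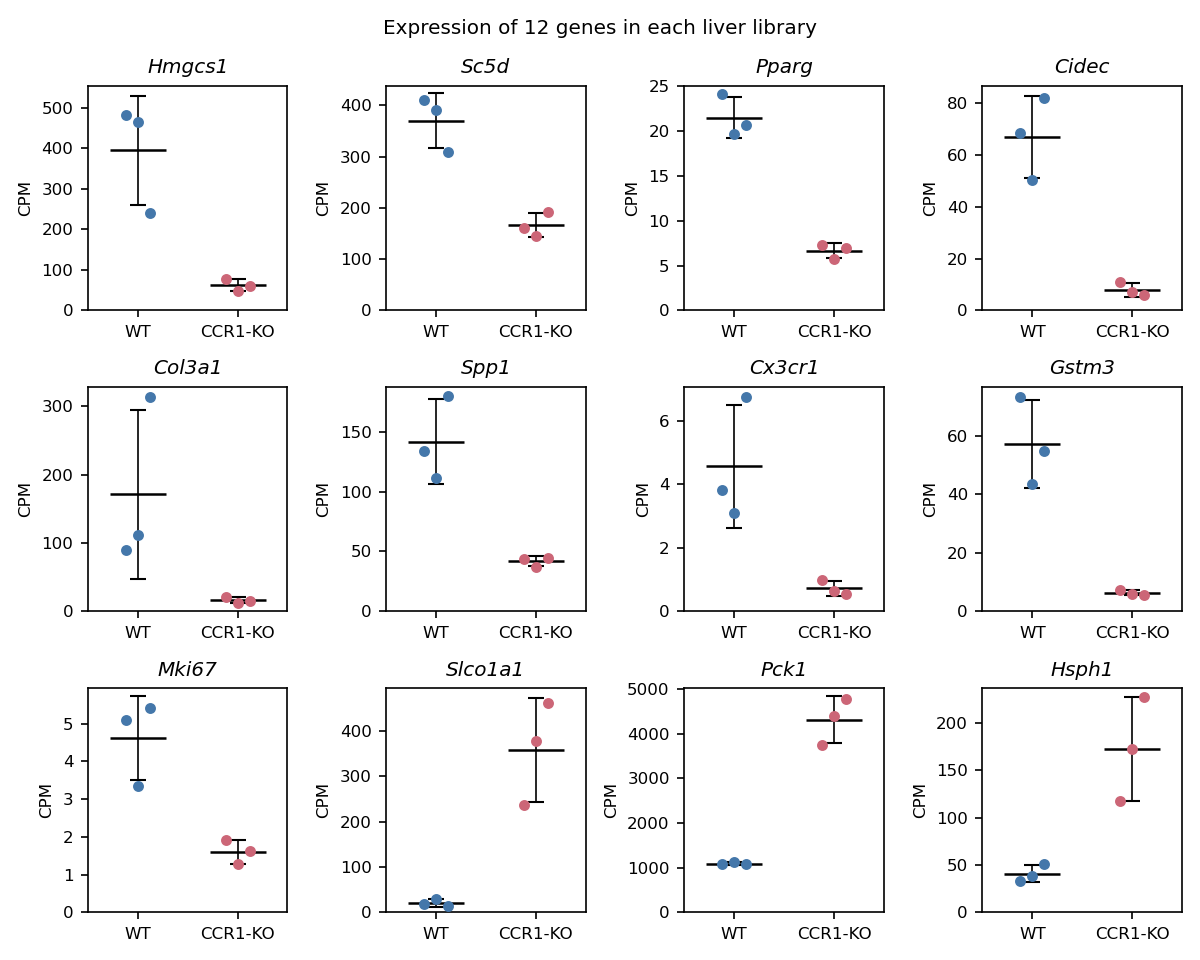
Expression of 12 named genes in CPM (vertical axes, linear, from 0, scaled per gene) in each liver library of the WT and CCR1-KO groups (horizontal axes). Points are libraries, the long line is the group mean and the error bar is 1 SD (n = 3). For each of the 12 genes the 2 groups do not overlap. Slco1a1, Pck1 and Hsph1 are higher in CCR1-KO and the other 9 are lower.

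Genes of hepatic stellate cells and fibrosis fell together. Of 39 tested, 17 fell, 0 rose and 22 did not pass. Adjusted over the list alone, 29 were lower (median log2 fold change -1.17, camera adjusted p = 2.3e-14, and adjusted p = 0.36 with an estimated correlation). The fibrillar collagen gene Col3a1 fell to 16.1 ± 4.27 against 171 ± 123 CPM (log2 fold change -3.41 ± 0.49, adjusted p = 0.013). The collagen cross-linking enzyme Loxl2 had 2.47 ± 0.201 against 8.48 ± 3.17 CPM (log2 fold change -1.78 ± 0.28, adjusted p = 0.016). The matrix protein Sparc had 30.6 ± 2.82 against 92.8 ± 35.9 CPM (log2 fold change -1.60 ± 0.25, adjusted p = 0.017), and the mesenchymal filament Vim had 15.2 ± 2.08 against 34.4 ± 10.1 CPM (log2 fold change -1.18 ± 0.21, adjusted p = 0.024). Without CCR1-KO replicate 66 none of these 4 passed, and without WT replicate 63 Col3a1 was the only one that did. The WT libraries were far apart for Col3a1, as the SD shows. Markers of bile duct cells and ductular reaction also fell, 4 of 20 tested with 0 higher and 16 not past the threshold. The count was 8 lower and 1 higher adjusted over the list alone (median log2 fold change -0.66, camera adjusted p = 3.4e-06, and adjusted p = 0.31 with an estimated correlation). Those past the threshold over all genes included Sprr1a, Spp1 (osteopontin, 41.8 ± 4.07 against 142 ± 35.2 CPM, log2 fold change -1.76 ± 0.19, adjusted p = 0.0074) and Cd24a (log2 fold change -1.34 ± 0.22, adjusted p = 0.017). In the endothelial list 2 of 23 tested genes fell, Plvap (log2 fold change -0.79 ± 0.15, adjusted p = 0.027) and Cd34 (log2 fold change -1.91 ± 0.45, adjusted p = 0.049), and 0 rose (median log2 fold change -0.36, camera adjusted p = 0.0051, and adjusted p = 0.74 with an estimated correlation). Both were also lower adjusted over the list alone. The list's call was lost without WT replicate 62 (adjusted p = 0.10), and that of the bile duct list with array weights (adjusted p = 0.059).

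The series title places macrophage activation and mTORC1 signalling at its centre, and macrophage genes moved in part. Of 26 tested genes of monocyte-derived and lipid-associated macrophages, 10 fell, 0 rose and 16 did not pass. Of the same genes, 18 were lower adjusted over the list alone (median log2 fold change -1.02, camera adjusted p = 2.5e-13, and adjusted p = 0.31 with an estimated correlation). The 4 with the smallest p were Apoc2 (69.1 ± 9.26 against 189.6 ± 15.5 CPM, log2 fold change -1.46 ± 0.14, adjusted p = 0.0045), Cd63 (4.75 ± 1.45 against 24.3 ± 10.3 CPM, log2 fold change -2.35 ± 0.34, adjusted p = 0.013), Fabp4 and Mmp14 (log2 fold change -1.03 ± 0.17, adjusted p = 0.018). Apoc2 is also made by hepatocytes, and 10 of the 26 genes also stood in other lists. The Kupffer cell and general macrophage list did not pass (median -0.34, camera adjusted p = 0.40). Of its 24 tested genes 2 rose, 0 fell and 22 did not pass. The scavenger receptor Cd163 rose to 13.1 ± 3.19 against 5.05 ± 1.99 CPM (log2 fold change 1.37 ± 0.32, adjusted p = 0.048), a call that was lost in each of the 6 fits without 1 library. Those that did not pass included Cd68 at 6.72 ± 2.57 against 13.99 ± 2.002 CPM (adjusted p = 0.068) and Aif1 at 2.01 ± 1.22 against 4.03 ± 0.678 CPM (adjusted p = 0.19); 2 were higher and 1 lower adjusted over the list alone. Neither activation list passed, M1-type (median -0.16, camera adjusted p = 0.87) or M2-type (median -0.25, camera adjusted p = 0.56). Slc7a2 rose in the M1-type list of 18 (log2 fold change 1.46 ± 0.32, adjusted p = 0.039). There were 1 higher and 0 lower adjusted over the list alone. In the M2-type list of 14, Socs2 and Cd163 rose and Tgm2 and Tgfb1 fell (Socs2 log2 fold change 2.28 ± 0.51, adjusted p = 0.043; Tgm2 -0.92 ± 0.18, adjusted p = 0.029; Tgfb1 -1.03 ± 0.25, adjusted p = 0.049). There were 3 higher and 3 lower adjusted over the list alone.

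Chemokine genes as a list did not pass (median -0.57, camera adjusted p = 0.082; 0 of 23 past the threshold and 0 adjusted over the list alone), with Ccl4 at 0.299 ± 0.0794 against 0.768 ± 0.195 CPM (adjusted p = 0.11) and Ccl3 at 0.262 ± 0.108 against 0.651 ± 0.211 CPM (adjusted p = 0.18). The list passed in 7 of the alternatives, with these adjusted p-values. In 4 of them it was limma with median-ratio scaling (0.010), FPKM rescaled to a common sum (0.038), quantile normalization (0.014) and array weights (0.046). The others were edgeR with no filter on low counts (0.022), and the fits without WT replicate 63 (0.010) and without CCR1-KO replicate 65 (5.5e-04). The 17 tested chemokine receptors other than Ccr1 were lower as a list (median log2 fold change -0.48, camera adjusted p = 0.041, and adjusted p = 0.65 with an estimated correlation). That call was lost in 16 of 25 alternatives, among them 8 of the 9 limma fits (adjusted p = 0.22 on deposited FPKM), DESeq2 (0.12), no scaling factors (0.27), upper-quartile scaling (0.066) and the fit without CCR1-KO replicate 66 (0.21). Cx3cr1, a receptor of monocytes whose gene lies within 5 Mb of Ccr1, was the 1 gene that passed (0.727 ± 0.243 against 4.56 ± 1.92 CPM, log2 fold change -2.64 ± 0.39, adjusted p = 0.014), and 2 were lower adjusted over the list alone. Of 38 tested mTORC1 pathway components, Mlst8, a subunit of both mTOR complexes, fell (7.27 ± 1.42 against 12.7 ± 1.04 CPM, log2 fold change -0.80 ± 0.18, adjusted p = 0.041). The kinase Sgk1, also in the list of immediate early and glucocorticoid genes, rose (23.6 ± 1.87 against 16.4 ± 1.30 CPM, log2 fold change 0.52 ± 0.12, adjusted p = 0.047). Mlst8 and Sgk1 each passed in 1 of the 6 fits without 1 library. Over 24 alternatives, the call was lost in 17 for Sgk1 and in 7 for Mlst8. Neither passed adjusted over the list alone, and the list did not pass (median 0.07, camera adjusted p = 0.76). Its mean was -0.04, of opposite sign to its median. Castor2 (log2 fold change -1.14 ± 0.33, adjusted p = 0.082) and Rictor (log2 fold change 0.91 ± 0.27, adjusted p = 0.084) did not pass. Rictor is a subunit of the other mTOR complex and not of mTORC1, so the list is wider than mTORC1 itself. These are transcript levels and do not measure mTORC1 activity.

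**Figure D3:**
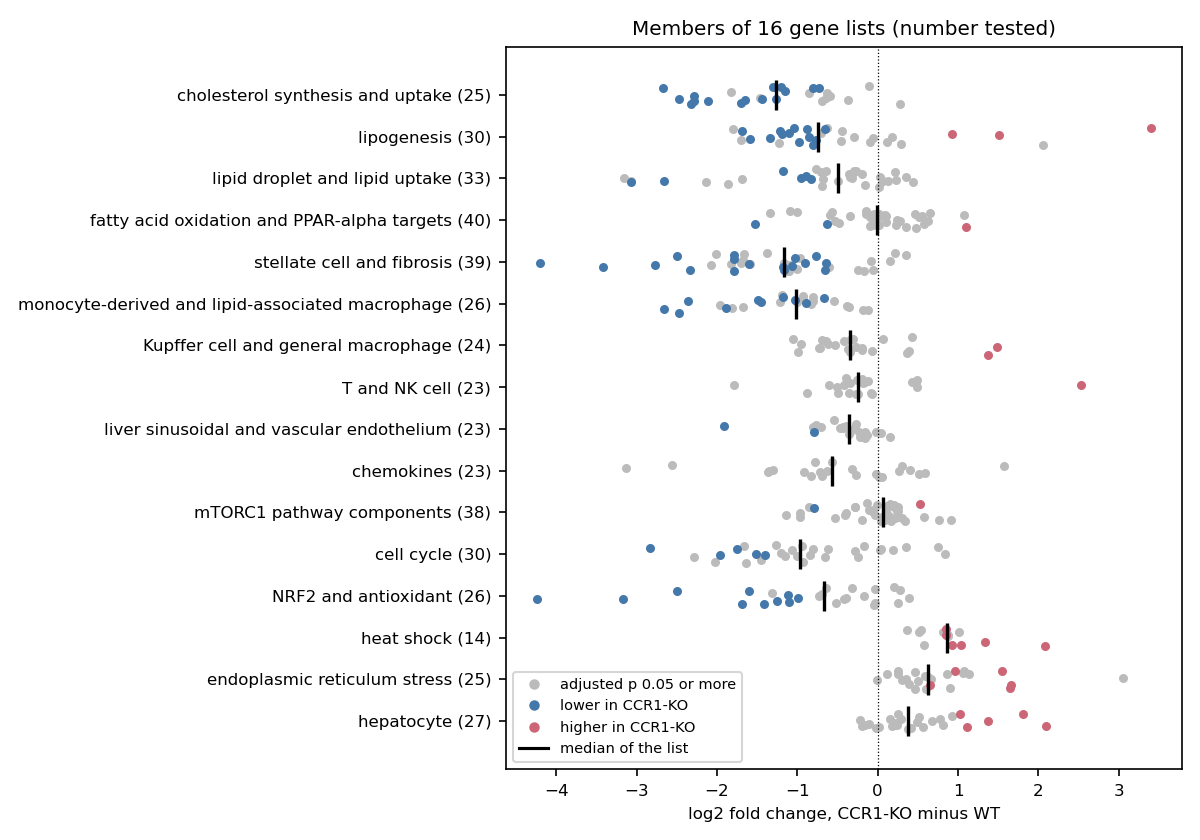
Log2 fold changes of CCR1-KO over WT (horizontal axis) for the tested members of 16 gene lists (vertical axis, number of tested genes in parentheses). Each point is a gene, coloured by whether its adjusted p was under 0.05 and by direction, and the black line is the median of the list. The cholesterol synthesis list has the lowest median of these 16, -1.26, and the heat shock list the highest, 0.86.

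Among other immune lists, 4 of 34 tested interferon response genes fell (Oasl1, Ifit2, Ifi27l2a and Ifit3, with log2 fold changes of -0.91, -1.46, -1.78 and -0.88) and 0 rose. Adjusted over the list alone, 4 were lower (median log2 fold change -0.43, camera adjusted p = 0.0029, and adjusted p = 0.75 with an estimated correlation). The interferon call was lost with limma on genes of FPKM 1 or more (adjusted p = 0.059) and without CCR1-KO replicate 67 (adjusted p = 0.073). The MHC class II list (median log2 fold change -0.65, camera adjusted p = 0.024, and adjusted p = 0.80 with an estimated correlation) and the B and plasma cell list (median log2 fold change -1.09, camera adjusted p = 0.017, and adjusted p = 0.62 with an estimated correlation) were lower without any single gene past the threshold, over all genes or adjusted over the list alone, in 12 and 17 tested genes. The MHC class II call was lost in 14 of 26 alternatives, among them the limma fit on deposited FPKM (adjusted p = 0.22), DESeq2 (0.15), no scaling factors (0.18) and the fit without CCR1-KO replicate 66 (0.22). The B and plasma cell call was lost in 8 of 17, among them DESeq2 (adjusted p = 0.060), no scaling factors (0.15) and the fits without WT replicate 63 (0.067) and CCR1-KO replicate 66 (0.071). The smallest adjusted p in them was that of Ifi30 (log2 fold change -0.76 ± 0.20, adjusted p = 0.064) and of Ighm (log2 fold change -1.09 ± 0.33, adjusted p = 0.095). The lists of T and NK cells (median -0.25, camera adjusted p = 0.94), neutrophils (median -0.19, camera adjusted p = 0.63), dendritic cells (median -0.48, camera adjusted p = 0.13) and the TNF and NF-kappaB response (median -0.32, camera adjusted p = 0.63) did not pass. Cd4 alone passed among 23 T and NK cell genes, and it was higher in CCR1-KO (2.16 ± 0.515 against 0.371 ± 0.0726 CPM, log2 fold change 2.53 ± 0.34, adjusted p = 0.011). Cebpd (19.1 ± 2.89 against 5.63 ± 0.0480 CPM, log2 fold change 1.76 ± 0.15, adjusted p = 0.0033) and Nfkbia (log2 fold change 0.82 ± 0.13, adjusted p = 0.017) rose in the TNF and NF-kappaB list of 28, with 2 higher and 1 lower adjusted over the list alone.

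Hepatocyte genes were higher. Of 27 tested, 5 rose, 0 fell and 22 did not pass. The count was 9 higher adjusted over the list alone (median log2 fold change 0.37, camera adjusted p = 3.4e-06, and adjusted p = 0.32 with an estimated correlation). The 5 past the threshold over all genes were the serpins Serpina3k (14411 ± 3563 against 3383 ± 455 CPM, log2 fold change 2.09 ± 0.23, adjusted p = 0.0080) and Serpina1a, which both have close paralogs, the tyrosine-degrading enzymes Tat (1652 ± 598 against 473 ± 3.69 CPM) and Hpd (2178 ± 479 against 1074 ± 106 CPM), and the urea cycle enzyme Cps1 (log2 fold change 1.37). The list's median was below 0 with limma under rescaling to a common sum (-0.10) and quantile normalization (-0.34, adjusted p = 0.28). Albumin did not pass (log2 fold change -0.16 ± 0.18, adjusted p = 0.63). In the list of sex-biased liver genes 14 of 34 tested rose, 4 fell and 16 did not pass. Of the same genes, 17 were higher and 6 lower adjusted over the list alone (median log2 fold change 1.27, camera adjusted p = 2.6e-04, and adjusted p = 0.31 with an estimated correlation). The list pools male-biased and female-biased genes. Its median and camera direction therefore depend on how many of each it holds, and do not measure a shift of sex bias. Those that rose included the near-identical copies Mup1, Mup3, Mup7, Mup11, Mup12 and Mup17. Slco1a1 (358 ± 114 against 21.1 ± 8.38 CPM, log2 fold change 4.09 ± 0.37, adjusted p = 0.0033) and Hsd3b5, which are known as male-biased, rose. Cyp2a4 (1.62 ± 0.651 against 21.02 ± 4.33 CPM, log2 fold change -3.70 ± 0.33, adjusted p = 0.0033) and Hao2, which are known as female-biased, fell, as did Cyp2b13 and Ntrk2 (log2 fold changes -3.66 and -2.12). Slco1a1, Hsd3b5, Cyp2a4 and Hao2 passed in every fit that left out 1 library. The list did not pass without Mup, mitochondrial and 18S rRNA genes (adjusted p = 0.25), a fit that also takes out its Mup members.

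The bile acid and sterol efflux list did not pass as a whole (median 0.09, camera adjusted p = 0.32), with 5 of 34 tested higher and 2 lower, and 6 higher and 4 lower adjusted over the list alone. Cyp27a1 (541 ± 15.04 against 291 ± 37.3 CPM, log2 fold change 0.89 ± 0.14, adjusted p = 0.016) and Cyp7b1 (335 ± 212 against 30.5 ± 4.30 CPM, log2 fold change 3.46 ± 0.55, adjusted p = 0.017), enzymes of the alternative route of bile acid synthesis, rose. Cyp7b1 also stood in the list of sex-biased liver genes. Each passed in 2 of the 6 fits without 1 library. Over 24 alternatives, the call was lost in 12 for Cyp27a1 and in 5 for Cyp7b1. The drug pump Abcb1a fell (log2 fold change -1.62 ± 0.27, adjusted p = 0.018). Cyp7a1, the rate-limiting enzyme of the classic route, was at 70.6 ± 29.3 against 153 ± 80.7 CPM and did not pass (adjusted p = 0.19). In the list of gluconeogenesis, glycogen and insulin signalling, 8 of 26 tested rose, 0 fell and 18 did not pass. Adjusted over the list alone, 10 were higher and 2 lower (median log2 fold change 0.20, camera adjusted p = 3.0e-09, and adjusted p = 0.31 with an estimated correlation). Those past the threshold over all genes included Pck1, which encodes a rate-controlling enzyme of gluconeogenesis (4311 ± 525 against 1095 ± 34.1 CPM, log2 fold change 1.98 ± 0.16, adjusted p = 0.0024), Igfbp1 (469.9 ± 119 against 46.5 ± 11.9 CPM, log2 fold change 3.34 ± 0.25, adjusted p = 0.0022) and Ppp1r3g. Median and test parted under some scalings, with medians of -0.11, -0.28 and -0.07 in the limma fit on deposited FPKM, with rescaling to a common sum and with no scaling factors. The glycolysis list did not pass (median -0.29, camera adjusted p = 0.087), with Pfkfb3 higher (log2 fold change 2.45 ± 0.41, adjusted p = 0.019) and Aldoc and Gpi1 lower (log2 fold changes -1.40 and -0.45) among 20, and 2 higher and 10 lower adjusted over the list alone. Gpi1 passed in 0 of the 6 fits without 1 library. Zonation lists did not pass, pericentral (median -0.33, camera adjusted p = 0.43; Cyp27a1 higher and Rhbg lower of 23, and 5 higher and 8 lower adjusted over the list alone) or periportal (median 0.19, camera adjusted p = 0.11; 4 higher and 3 lower of 23, and 7 higher and 4 lower adjusted over the list alone). In the periportal list Pck1 rose, while Apoa4 (584 ± 282 against 4198 ± 379 CPM), Aldh1b1 and Hsd17b13 fell. The xenobiotic list did not pass (median 0.14, camera adjusted p = 0.71, direction lower, opposite to its median), with 4 of 32 higher and 3 lower, and 6 higher and 9 lower adjusted over the list alone. Cyp2a4, Cyp2b13 and Cyp3a59 (log2 fold change -2.30 ± 0.47, adjusted p = 0.032) fell and Sult2a8 rose (log2 fold change 1.40 ± 0.26, adjusted p = 0.024).

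Genes of the NRF2 antioxidant programme fell, 10 of 26 tested with 0 higher and 16 not past the threshold. The count was 13 lower adjusted over the list alone (median log2 fold change -0.67, camera adjusted p = 2.0e-11, and adjusted p = 0.31 with an estimated correlation). The glutathione transferases Gstm3 (6.36 ± 0.837 against 57.1 ± 15.1 CPM, log2 fold change -3.17 ± 0.22, adjusted p = 0.0022) and Gstm2 (23.7 ± 5.43 against 76.5 ± 16.7 CPM, log2 fold change -1.69 ± 0.21, adjusted p = 0.0098), which have paralogs, fell with the sulfiredoxin Srxn1 (34.01 ± 5.04 against 73.7 ± 6.69 CPM) and the quinone reductase Nqo1 (3.25 ± 0.895 against 9.86 ± 0.474 CPM). Chaperone genes rose instead. Of 14 tested heat shock genes 6 rose, 0 fell and 8 did not pass. Of the same genes, 7 were higher adjusted over the list alone (median log2 fold change 0.86, camera adjusted p = 1.3e-09, and adjusted p = 0.31 with an estimated correlation). Among the 6 were Hsph1 (173 ± 54.5 against 40.9 ± 9.10 CPM, log2 fold change 2.08 ± 0.26, adjusted p = 0.0098), Hsp90aa1 (354 ± 56.5 against 139.8 ± 41.1 CPM), Hspa8 (2086 ± 327 against 1019 ± 89.8 CPM) and Chordc1 (log2 fold change 0.92 ± 0.13, adjusted p = 0.012). Of 25 tested endoplasmic reticulum stress genes 5 rose, 0 fell and 20 did not pass. Adjusted over the list alone, 18 were higher (median log2 fold change 0.62, camera adjusted p = 5.5e-10, and adjusted p = 0.36 with an estimated correlation). Past the threshold over all genes were Herpud1 (680.0 ± 204 against 233 ± 6.34 CPM, log2 fold change 1.54 ± 0.22, adjusted p = 0.013), Dnajb11, Creld2, Sdf2l1 and Dnajc3, with log2 fold changes of 0.96, 1.66, 1.64 and 0.65 for the last 4. In the 6 fits without 1 library, Herpud1 passed in 3, Sdf2l1 in 2, and Dnajb11, Creld2 and Dnajc3 in 1 each. Over 24 alternatives, the call was lost in 17 for Dnajc3 and in 13 for Dnajb11. Under 7 scalings the list's median ran from 0.12 to 0.64. The ATF4 list did not pass (median -0.03, camera adjusted p = 0.63), with Chac1 higher (10.03 ± 3.84 against 2.86 ± 1.27 CPM) and Aldh1l2 lower (0.00558 ± 0.00966 against 0.275 ± 0.103 CPM) among 27, and 3 higher and 5 lower adjusted over the list alone. Cell cycle genes fell, 5 of 30 tested with 0 higher and 25 not past the threshold. The count was 13 lower adjusted over the list alone (median log2 fold change -0.97, camera adjusted p = 1.2e-06, and adjusted p = 0.31 with an estimated correlation). Those that fell over all genes were Mki67 (1.61 ± 0.319 against 4.62 ± 1.11 CPM, log2 fold change -1.52 ± 0.28, adjusted p = 0.024), Mcm3, Mcm2, Cenpf and Ccnb2, with log2 fold changes of -1.40, -1.74, -2.83 and -1.97 for the last 4. In the 6 fits without 1 library, Mcm3 and Mcm2 passed in 2, and Mki67, Cenpf and Ccnb2 in 1 each. The cell cycle call was lost with limma on genes of FPKM 1 or more (adjusted p = 0.083) and with array weights (adjusted p = 0.17). The apoptosis list (median -0.14, camera adjusted p = 0.71; 0 of 27, also adjusted over the list alone) and the acute phase list (median 0.13, camera adjusted p = 0.35; Itih3 alone higher of 27, 0 adjusted over the list alone, log2 fold change 0.69 ± 0.16, adjusted p = 0.044) did not pass. Of 32 tested lysosome and autophagy genes 5 fell (Cd63, Hexa, Lipa, Ctsd and Ctsa), 0 rose and 10 were lower adjusted over the list alone (median log2 fold change -0.08, camera adjusted p = 0.022, and adjusted p = 0.31 with an estimated correlation).

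Genes of the immediate early and glucocorticoid response rose, 5 of 26 tested with 0 lower and 21 not past the threshold, and 5 higher and 0 lower adjusted over the list alone (median log2 fold change 0.67, camera adjusted p = 8.7e-06, and adjusted p = 0.32 with an estimated correlation). They were Per1 (48.9 ± 6.66 against 12.5 ± 1.54 CPM, log2 fold change 1.96 ± 0.15, adjusted p = 0.0022), a clock gene that glucocorticoids also raise, Tat, Tsc22d3 (log2 fold change 1.26 ± 0.21, adjusted p = 0.019), Fkbp5 (log2 fold change 2.64 ± 0.50, adjusted p = 0.026) and Sgk1. In the 6 fits without 1 library, Per1 passed in 6, Tat in 3, Tsc22d3 in 2, and Fkbp5 and Sgk1 in 1 each. Of 19 tested clock genes Per1 alone rose, also adjusted over the list alone, and 0 fell (median log2 fold change 0.44, camera adjusted p = 0.0029, and adjusted p = 0.31 with an estimated correlation). The median of the clock list was below 0 in the limma fit on deposited FPKM (-0.04) and with rescaling to a common sum (-0.21), where the list passed. The call was lost with limma under median-ratio scaling (adjusted p = 0.067) and quantile normalization (adjusted p = 0.081).

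Signs of RNA quality and of other tissues were compared in the same way. On the first principal component, which held 48.4% of the variance, the WT libraries lay at -59.8, -47.4 and -59.6, and CCR1-KO replicates 65, 66 and 67 at 12.6, 76.4 and 77.8. Mitochondrial genes took 6.25% to 10.9% of reads, highest in WT replicate 62, and the groups overlapped (8.09% ± 2.43 in WT, 7.34% ± 1.21 in CCR1-KO; exact two-sided permutation p = 0.70, n = 3). The list of mitochondrially encoded messenger RNA did not pass (median 0.16, camera adjusted p = 0.44), and neither did the nuclear-encoded oxidative phosphorylation list (median 0.09, camera adjusted p = 0.14). The gene model CT010467, which holds 18S ribosomal RNA sequence, took 0.102%, 0.111% and 0.334% of reads in the WT libraries, and 0.114%, 0.145% and 1.05% in the CCR1-KO libraries, highest in replicate 67. Ribosomal protein genes were higher as a list without any of 47 past the threshold over all genes or adjusted over the list alone (median log2 fold change 0.22, camera adjusted p = 0.0029, and adjusted p = 0.86 with an estimated correlation). The median of that list was below 0 with no scaling factors (-0.09), in the limma fit on deposited FPKM (-0.09) and with rescaling to a common sum (-0.26). Its call was lost in 13 of 26 alternatives, these 3 among them, and without WT replicate 62 or CCR1-KO replicate 66. Adipose tissue markers were lower (median log2 fold change -1.17, camera adjusted p = 0.020, and adjusted p = 0.31 with an estimated correlation), with Cidec, Fabp4 and Aqp7 lower and Pck1 higher among 7, and 1 higher and 4 lower adjusted over the list alone; 3 of the 7 also stood in other lists. The call was lost in each of the 10 limma fits, with DESeq2 (adjusted p = 0.081), with no scaling factors (adjusted p = 0.064) and without CCR1-KO replicate 66 (adjusted p = 0.059). Lists of red cells (median -0.08, camera adjusted p = 0.62; Car2 lower of 9, also adjusted over the list alone, log2 fold change -1.95 ± 0.25, adjusted p = 0.0098) and muscle (median -0.24, camera adjusted p = 0.68; 0 of 5, also adjusted over the list alone) did not pass. The pancreas list had 3 tested genes, too few for a test. Of these Cela1 was higher in CCR1-KO (log2 fold change 1.22, adjusted p = 0.030), also adjusted over the list alone, and 0 fell. Among lists that did not pass, the sign of the median also depended on scaling: it turned in 5 of 7 scalings for the list of the Ccr1 region, in 3 for mTORC1 components, in 1 for fatty acid oxidation, and in 4 each for the acute phase, bile acid, periportal, xenobiotic, mitochondrial messenger RNA and oxidative phosphorylation lists.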

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

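Alternatives to the edgeR count test that were added after the data were seen were the limma fit on log2(FPKM + 0.5), the other edgeR scalings and filters, the robust quasi-likelihood fit, DESeq2, the fit without Mup, mitochondrial and 18S rRNA genes, and every alternative for the annotation terms. Among the values of named genes under the alternatives, 4111 of 4938 stayed on the same side of the threshold without a reversal. Of the rest, 611 lost the threshold, 215 passed it newly and 1 reversed. For gene lists these counts were 1034 of 1163, 103, 23 and 3. A change of sign counted as reversed only where the edgeR test or the alternative passed. Medians of lists that turned with scaling, as given above, are therefore not all counted here. The reversed lists were mTORC1 (median -0.19) with limma and no filter on low FPKM, and mitochondrial messenger RNA (-0.50) and hepatocyte (-0.34) with quantile normalization. The reversed gene was Clock (-0.36) with array weights. The cause was not tested.

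The count of changed genes left the range of 1.5 times the 1141 of the edgeR test in 4 of the settings with all libraries. It was 239 (67 higher, 172 lower) with limma and no filter on low FPKM, 6719 (969 higher, 5750 lower) with array weights, 735 (314 higher, 421 lower) with no filter on low counts, where more genes were tested, and 2347 (1035 higher, 1312 lower) with DESeq2. Of the DESeq2 genes 1123 were among the 1141, but on simulated data 50 of its 174 calls were false. The split by direction moved with scaling. Higher and lower genes numbered 223 and 1088 in the limma fit on deposited FPKM, 225 and 1124 with pseudocount 1, 217 and 969 with pseudocount 0.1, 207 and 955 with FPKM of 1 or more, 161 and 1083 with FPKM rescaled to a common sum, 216 and 1073 with the robust limma fit, and 219 and 857 with no scaling factors. They numbered 433 and 643 with limma under median-ratio scaling and 431 and 658 under quantile normalization, close to the balance of the edgeR test, so the balance followed scaling. With each library left out in turn, the count ran from 102 to 2419 (36 to 1010 higher, 66 to 1409 lower), lowest without WT replicate 63 and highest without CCR1-KO replicate 65.

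Between 16 and 28 lists passed, against 23, except for 0 with an estimated correlation and 9 with directional fry. The 217 annotation terms became 100 in the limma fit on deposited FPKM and in its robust form, 95 with pseudocount 1, 89 with pseudocount 0.1, 1017 with no filter on low FPKM, 81 with FPKM of 1 or more, 107 with FPKM rescaled to a common sum, 115 with array weights, 139 with no scaling factors, 437 with no filter on low counts, 0 with an estimated correlation, and 106 to 302 with a library left out. Ccr1 passed with no scaling factors (-3.05, adjusted p = 0.0498) and with DESeq2 (-2.74, adjusted p = 0.0050); over its 14 alternatives the log2 fold change ran from -3.23 to -0.60 and the adjusted p from 0.0050 to 0.24. It fell below the FPKM filters and below a minimum count of 50, so those settings gave no value for it. Depth limits Ccr1, with 4 to 123 reads in a library. Planned fits that need the other 6 libraries were not run.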

Other observations

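Annotation terms that the table pairs with genes were tested beside the lists. With camera's preset correlation 132 of 4867 terms were lower in CCR1-KO and 85 were higher, and 0 passed with an estimated correlation (smallest adjusted p = 0.90). Sphingolipid metabolism, a theme outside the fixed lists, was lower in Reactome, with 11 of 73 tested genes lower and 0 higher (adjusted p = 6.6e-04, and 0.90 with an estimated correlation). Protein processing in the endoplasmic reticulum was higher, with 11 of 155 tested genes higher and 1 lower (adjusted p = 9.0e-04, and 0.90 with an estimated correlation). Arginine biosynthesis was higher, with 4 of 18 tested genes higher and 0 lower (adjusted p = 0.021), as was the spliceosome, with 5 of 128 higher and 0 lower (adjusted p = 0.030); both had an adjusted p of 0.90 with an estimated correlation.

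The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The genotype split gave 1141 changed genes and the highest of the others gave 2, so 1 of the 10 splits gave as many. For gene lists the genotype split gave 23 and the highest other 31, and 4 of 10 splits gave as many. For terms it gave 217 and the highest other 306, and 3 of 10 gave as many. As many list and term calls at the preset correlation were thus reached by some other splits. The split with 31 lists and 306 terms put CCR1-KO replicate 65 with WT replicates 62 and 64. Each of the other splits has an unequal mix of genotypes on its sides, so part of the genotype difference remains in it. They cannot show whether such calls arise without that difference.

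All the tests in the rest of this part were chosen after the results they concern were seen. Both Nnt gene models differed between the groups, 1 higher and 1 without reads in CCR1-KO. Reads moving between the models would leave their sum alone, but the sum was higher in CCR1-KO, at 140.5 ± 10.8 against 64.6 ± 1.41 CPM (n = 3, log2 fold change 1.12 ± 0.11 SE, edgeR adjusted p = 0.0054), which argues against that as the whole cause. Of 9 genes recalled from general knowledge as differing between C57BL/6J and C57BL/6N, without a reference to check them, 4 passed (Wdfy1, Entpd4, Ide and Mmd2, with log2 fold changes of 1.17, -0.99, -0.62 and -1.55) and 5 did not, where 0.579 was the count by chance (exact one-sided hypergeometric p = 0.0017). With 1 library left out, 0 to 3 of the 9 passed, and the p was under 0.05 in 2 of the 6 fits. A substrain difference may run along with genotype, and a part of the changed genes, the Nnt models among them, could follow it. Genotype and background cannot be separated in these 6 libraries. Within 5 Mb of Ccr1, 5 of 76 tested genes changed (6.58% against 6.44% elsewhere, two-sided Fisher's exact p = 1). They were Csrnp1, Ano10, Zfp445, the receptor gene Cx3cr1 and a predicted gene, and sequence linked to the Ccr1 locus was not excluded for them. Within 5 Mb of Nnt 2 of 30 changed, Tmem267 and the cholesterol synthesis gene Hmgcs1, both lower (6.67% against 6.44% elsewhere, two-sided Fisher's exact p = 1). Sequence linked to the Nnt locus was not excluded for these either.

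Genes of stellate cells, matrix and lipid-associated macrophages were lower in CCR1-KO. A larger share of hepatocyte RNA would lower every other cell type alike, but their median was -1.12 against -0.32 for the Kupffer cell, endothelium and T and NK cell lists (difference -0.80, 95% bootstrap interval over genes -1.12 to -0.64). In single libraries that difference ran from -0.14 to 1.29 in WT and from -0.79 to -0.12 in CCR1-KO, so the groups overlapped (exact two-sided permutation p = 0.20, n = 3), and a changed mix of cells cannot be told apart from a change within cells. The condition on libraries was added to the test after their overlap was seen. Scaling shifted by the Mup transcripts is argued against as the whole cause. Mup genes took at most 16.2% of reads in CCR1-KO and at least 1.02% in WT, which allows a log2 shift of other genes of -0.24 at most. With no scaling factors the lists' median was -1.43 (95% bootstrap interval -1.73 to -1.24). With the share of Mup reads taken out, the groups still did not overlap in the lists' mean in single libraries. This test replaced 2 others after their values were seen.

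Some glucocorticoid and fasting-type genes were higher in CCR1-KO, 12 genes with a median log2 fold change of 1.86. They were picked from 2 fixed lists because they passed as higher; 49 tested members of these lists, called or not, had a median of 0.49. A longer fast stays open. Of genes that fasting raises, 8 others had a median of 0.24 with 1 past the threshold, a difference of -1.61 from the 12 (95% bootstrap interval -2.36 to -0.67), but of -0.25 from the 49 (-0.80 to 0.55). Srebf1, which fasting lowers, was lower (log2 fold change -0.80, adjusted p = 0.037). The comparison with the 49 was added after the first was seen. A different hour of harvest stays open too. The score of clock genes of opposite phase was higher by 0.97 in CCR1-KO, but it was 1.65, 4.80 and 5.34 in replicates 65, 66 and 67 against 2.85 to 3.06 in WT, so the CCR1-KO libraries differed more among themselves (3.68) than the groups did. The hour of harvest and genotype cannot be told apart here, and stress at harvest was not tested.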
